A study of Mus musculus with 19 samples.

How the data were processed

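The study used mice in which cells of the neural crest or of the autonomic lineage carried a fluorescent label. Per the labels' protocols, cardiac cells of E12.5 to E16.5 came from a Wnt1-Cre line with a tdTomato reporter, those of E18.5 and P56 from a Baf53b-Cre line with a density gradient, the atrial regions from a Wnt1-Cre line with a GFP reporter, and the intestine, enteric, lung, pancreas and coculture libraries from a Phox2b-Flpo line. Tissue was digested with trypsin, collagenase and dispase and labelled cells were sorted. The atrial and intestine libraries held few or no cells classed by their markers as neuronal or glial, so such a sort cannot be assumed for them. The deposited files hold UMI counts per gene and cell barcode, which the authors made with Cell Ranger 7.1.0, per the file headers, on the mm10 genome build, per the submitters' processing notes. The counts were whole numbers, not normalized, over 32285 genes, and 1 library stood in each matrix. How barcodes were filtered before deposit is not given in the sources used here. Gene positions are those of the GENCODE annotation of GRCm38, matched by gene identifier for 32158 of the 32285 genes. Reporter and recombinase sequences were not analysed here.

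The total per library lay between 34167621 and 173975086 UMIs and the median per barcode between 3282 (enteric library) and 50822 (intestine coculture 3). Cells with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept. Doublets were scored with Scrublet as in scanpy 1.11.5. Its automatic threshold called 0 doublets in 4 libraries, so in each library the highest scores were removed up to the expected rate, which took 1.31% to 13.5% of cells. Cells of each library were clustered on their own, on 30 principal components of 2000 variable genes, with 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9). A cluster took the class whose fixed markers scored highest, with a score of at least 0.5, a margin of 0.1 over the next class and at least 3 markers each detected in 10% of its cells. It stayed unnamed where its 10 leading genes went against the class.

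The naming rule went through 4 versions after the cluster tables had been seen and before any comparison between groups. Its thresholds kept clusters whose highest score was neuronal out of the class in the intestine cocultures. These were 104 cells in coculture 2, 179 in coculture 3, and 317 and 218 in coculture 4, led by genes such as Gal, Chrna3 and Hoxb5. With the highest score alone the neuron-like share was 8.27%, 31.8%, 34.3% and 30.6% in the 4 intestine cocultures, in place of 8.27%, 26.3%, 27.2% and 21.7%, and stayed at 11.8% and 22.4% in the heart cocultures. The neuron-like class held 188 to 1297 cells per coculture, 149 and 334 at E12.5 and 2999 and 1108 at E14.5. Other cells of the cocultures differed by organ. Smooth-muscle-like cells made up 80.9%, 46.0%, 49.6% and 44.2% of intestine cocultures and 13.8% and 15.8% of heart cocultures, which also held 10.1% and 4.46% cardiomyocyte-like and 6.97% and 27.0% mesothelium-like cells.

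Counts were summed per library over the cells of a class and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM, its own filter on low counts, Benjamini-Hochberg adjustment, threshold 0.05). Libraries with fewer than 20 cells of a class were left out. The tests, gene lists, markers and rule for named genes were fixed before the data were examined. The tests compared heart with intestine cocultures in neuron-like and mesenchyme-like cells and E14.5 with E12.5 in cardiac neuron-like and glia-or-progenitor-like cells. The summed neuron-like counts held 5108189 to 29903049 UMIs per coculture and 3048565 to 50939788 per cardiac library, and the mesenchyme-like counts 381640 to 5064470 UMIs. The biological coefficient of variation was 0.397 in cocultured neurons and 0.313 in cardiac neurons. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists with at least 3 measured genes. Comparisons with 1 library per group had no test, and their intervals are exact Poisson or Clopper-Pearson binomial intervals of 95%, from scipy 1.17.1, which cover counting error only. DESeq2 1.42.0, no filter on low counts, other cell filters, doublets kept, Leiden resolution 2, classes by markers without clusters, blocks and leaving out each library were tried as alternatives, chosen with the tests.

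Genes were named by a fixed rule. Of replicated comparisons it took up to 10 genes per direction by fold among those past the threshold with libraries apart and a mean of at least 20 CPM, and list members past the threshold. Genes without a proper symbol, mitochondrial, ribosomal, haemoglobin and sex-linked marker genes were left out. So were genes that failed a test for free RNA, which asks that the difference in the class exceed 0.2 times the difference of the same sign in the other cells of the libraries. This test removed 44 of the 340 genes in cocultured neurons. Without replicates the rule took at most 8 genes per direction, with at least 30 UMIs and a CPM ratio of at least 4 against each library of the other group, and for list members a ratio of at least 2. The comparison of ligands between atrium and intestine was an exception. It took every ligand with at least 30 UMIs and a ratio of at least 2, without the free-RNA test. Folds against a level of 0 use a floor of 3 counts per library.

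Dates in the library titles pair heart coculture 1 with intestine coculture 1 and heart coculture 2 with intestine coculture 3. Their deviations from the group means correlated at 0.775 and 0.764 across genes, and heart coculture 2 correlated at 0.747 with intestine coculture 4 of another date. The deviations of the 2 heart cocultures mirror each other by construction, so these values are not independent of each other. The date was used as a block beside the coculture results. Intestine cocultures 2 and 4 share no date with a heart coculture, so the blocked effect rests on the 2 pairs. Each blocked fit, by date or by number, left 1 residual degree of freedom. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 183 to 1487), so each counted as 1 sample. Each step was tested on simulated data with 100 genes changed by each fold. At 4-fold edgeR recovered 58% of changed genes in a simulation of the cocultured neurons (15609 genes), 72% of the cardiac neurons (13835 genes), 42% of the cardiac glia-or-progenitor-like cells (13754 genes) and 1% of the coculture mesenchyme-like cells (11498 genes). At 2-fold it recovered 5%, 6%, 2% and 0%. In the simulated cocultured neurons 17 of 100 genes called by DESeq2 were false calls, against 2 of 65 by edgeR. In the simulated cardiac neurons these were 9 of 90 and 4 of 82. The rule of size named 100 of 100 genes at 8-fold and 0 of 100 at 2-fold in each of 3 simulated comparisons. It also named 2 unchanged genes in the simulation of mesenchyme-like cells near against far. These counts had Poisson noise and no spread between libraries, so they cannot show how often such spread leads to a false call. A further alternative, neuron-like cells with at most 0.1% of UMIs from 38 organ markers, was added after the 340 genes and the marker shares had been seen, and no other value of that limit was run. That limit also removes neurons that express such genes themselves. Camera with each library left out in turn was also added after the data had been seen.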

Results

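Gene expression was measured in single cells of the mouse heart, intestine, lung and pancreas and in cocultures, to follow how neurons of the intrinsic nervous systems of these organs differ by age and by the organ cells around them. The 19 libraries were droplet libraries of the 10x Genomics 3' kind, in which each RNA molecule carries a unique molecular identifier (UMI). Cells of the intracardiac nervous system, the neurons and glia that lie in the heart wall, were taken at E12.5 (2 libraries), E14.5 (2 libraries), E16.5, E18.5 and P56 (1 library each). At E14.5 there was also 1 library each of atrial tissue near these neurons and far from them, and of intestine. Labelled cells of the enteric nervous system, lung and pancreas gave 1 library each as well. Enteric neurons of E13.5 embryos, sorted by a Phox2b-driven label, had been cocultured for 4 to 5 days with unlabelled cells of the intestine (4 libraries) or of the heart atria (2 libraries), at 3000 neurons and 6000 other cells per well. The libraries held between 34167621 (lung) and 173975086 UMIs (heart coculture 2) over 1879 to 19531 barcodes. The labels number the libraries of 1 group as biological replicates, with different dates in their titles, and p-values measure the spread between these libraries. Values are CPM, UMI counts summed over the cells of a class and scaled to the same total in each library, as mean ± SD over libraries, and log2 fold changes are given ± SE.

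The first comparison asked which genes differed between enteric neurons cultured with heart cells and the same kind of neurons cultured with intestinal cells. Extracellular matrix genes were higher as a list in neuron-like cells of the heart cocultures (camera adjusted p = 8.91e-34, and adjusted p = 0.0886 with an estimated correlation), and 10 genes were named by their fold. Col1a2, a chain of type I collagen, stood at 282 ± 76.5 CPM (n = 2) against 1.35 ± 0.67 CPM (n = 4), a log2 fold change of 7.63 ± 0.48 (edgeR adjusted p = 0.00201). Bgn, the matrix proteoglycan biglycan, stood at 231 ± 57.4 against 1.83 ± 0.47 CPM (log2 6.90 ± 0.28, edgeR adjusted p = 0.000645), and Gata6, a transcription factor of heart and gut mesoderm, at 42.8 ± 18.7 against 0.35 ± 0.25 CPM (log2 6.72 ± 0.52, edgeR adjusted p = 0.00407). Eln, the elastin gene, had the highest fold and an SD above its mean in the heart cocultures (279 ± 382 against 0.30 ± 0.08 CPM, log2 9.71 ± 1.48, edgeR adjusted p = 0.0278). The other named genes were Vamp5, Ptgis, Spon2, Tbx18, Tgm2 and Nid2, with log2 fold changes of 5.92 (Nid2) to 7.25 (Vamp5). Some of the 10 lay close to the limit of 0.2 in the free-RNA test. Nid2 stood at 49.0 against 0.72 CPM in neuron-like cells and at 275 against 35.1 CPM in the other cells. Tgm2 stood at 58.3 against 0.76 CPM and at 298 against 22.6 CPM. With the title date as a block 8 of the 10 passed, and Eln (edgeR adjusted p = 0.226) and Ptgis (edgeR adjusted p = 0.0674) did not. Neither passed without intestine coculture 2, 3 or 4, Ptgis did not pass without heart coculture 2, and Spon2 did not pass without intestine coculture 2. Of the 10, 5 passed with classes by markers, 4 with doublets kept, 2 with clusters named by their highest score alone and 0 with only the 4 libraries of shared dates. Tbx18, a transcription factor of the epicardium and its derivatives, stood at 22.6 ± 9.94 against 0.21 ± 0.19 CPM. On the GRCm38 genome Col1a2 (ENSMUSG00000029661) lies on chromosome 6 at 4504814 to 4541544, Bgn (ENSMUSG00000031375) on chromosome X at 73483602 to 73495933 and Gata6 (ENSMUSG00000005836) on chromosome 18 at 11052064 to 11085635, all protein-coding. In all, 340 of 15609 genes passed the threshold, 340 higher with heart cells and 0 lower (edgeR, 1326 genes at an unadjusted p under 0.05). Of the 340, 318 were also higher in the other cells of the heart cocultures than in those of the intestine cocultures, as with Col1a2, at 1390 against 57.9 CPM there, and all 340 were higher in the other cells of the heart cocultures than in the neuron-like cells there.

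Markers of organ cells moved with the group. In the heart cocultures 35.4% and 30.1% of neuron-like cells took more than 0.1% of their UMIs from 38 markers of mesenchyme, smooth muscle, cardiomyocytes and mesothelium, against 6.91%, 8.62%, 13.6% and 6.25% in the intestine cocultures. Among the remaining neuron-like cells, a restriction chosen after the 340 genes had been seen, Col1a2 stood at 18.9 ± 11.4 CPM and Bgn at 25.2 ± 13.9 against 1.49 ± 0.42 CPM, and 0 of 14719 genes passed (edgeR, 193 at an unadjusted p under 0.05). Col1a2 and 19 others of the 340 genes are among the 38 markers, so the selection itself lowers them. Over the other genes tested in both the median log2 fold change was 0.79 there against 2.99 in all neuron-like cells. There DESeq2 called 32 genes, 29 higher and 3 lower, and edgeR with the title date as a block called 146 (130 higher, 16 lower), of which 91 failed the test for free RNA of other cells. The 55 that passed it included Mgst1, a microsomal glutathione transferase (log2 2.47, edgeR adjusted p = 5.5e-05), Robo1, an axon guidance receptor (log2 1.11, edgeR adjusted p = 0.0365), and Htr3a, a subunit of the serotonin-gated channel (log2 0.89, edgeR adjusted p = 0.0318). Klhl1 was lower there (log2 -0.86, edgeR adjusted p = 0.0318). These 4 genes were chosen after their values were seen, and the blocked fit rests on the pairs of libraries with shared dates.

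**Figure D1:**
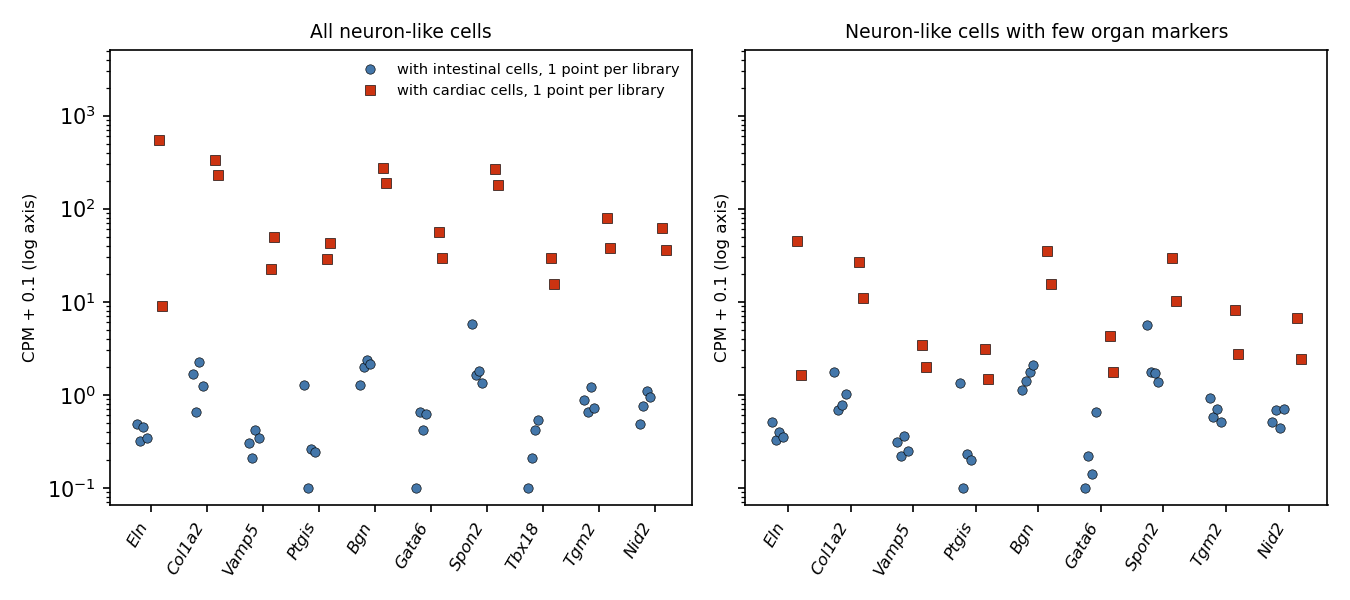
CPM on a log axis, with 0.1 CPM added, of the 10 named genes in neuron-like cells of each coculture library, 1 point per library, with all neuron-like cells at left and those with few organ markers at right. At left the 2 heart cocultures lay above the 4 intestine cocultures for each gene, and at right, where Tbx18 was not tested, the level with heart cells was lower for genes such as Bgn (25.2 against 231 CPM at left), which is not among the markers used to select the cells.

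The list members that passed the threshold were higher with heart cells. Of 30 lists 5 passed camera's set test, from an adjusted p of 8.91e-34 (extracellular matrix) to 0.000323 (guidance ligands), and 0 passed in camera with an estimated correlation between genes, the smallest adjusted p being 0.0886. Of 21 measured genes of the extracellular matrix, 8 rose over all genes tested and 14 adjusted over the list alone, among them Col1a1 (504 ± 38.0 against 12.6 ± 3.07 CPM) and Col4a1 (314 ± 44.7 against 12.9 ± 4.63 CPM). Of 17 neurotrophic ligands 3 rose (6 adjusted over the list alone), with Ngf, nerve growth factor, at 7.63 ± 1.66 against 0.17 ± 0.12 CPM, Edn1, endothelin 1, at 16.4 ± 0.42 against 0.72 ± 0.42 CPM, and Ntf5. Of 30 morphogen ligands 4 rose (7 adjusted over the list alone), Bmp4 standing at 21.4 ± 6.12 against 3.84 ± 0.65 CPM, beside Fgf2, Tgfb3 and Bmp6. Of 19 guidance ligands 4 rose (4 adjusted over the list alone), Cxcl12 with 44.8 ± 3.68 against 5.13 ± 1.40 CPM, and of 10 TGF-beta response genes 2 rose (4 adjusted over the list alone), Serpine1 with 64.5 ± 33.4 against 1.41 ± 0.58 CPM, and Ltbp2. In lists that did not pass, Meis2, Tbx20, Unc5b, Hes1 and Spry1 also rose, as did Kcnab1, which failed the free-RNA test. With the title date as a block 8 lists passed, the added ones being synaptic vesicle genes (camera, Down, adjusted p = 0.0254), cytoskeleton and axon growth genes (camera, Down, adjusted p = 0.00501) and cell cycle genes (camera, Up, adjusted p = 0.0108, against a median of -0.30 without the block). In neuron-like cells with few organ markers, extracellular matrix genes (camera adjusted p = 2.88e-06) and voltage-gated channels (0.00184) were up and cell cycle genes down (0.000509), each with an adjusted p of 0.802 with an estimated correlation. Of the matrix genes at an unadjusted p under 0.05 in edgeR there, Col1a1, Col1a2, Col4a1 and Col4a2 were higher but failed the free-RNA test. Lama4 was higher and passed it, and Tnc was lower and failed it. Col1a1 and Col1a2 are also among the markers used to select the cells. The other 4 lists did not pass there (camera adjusted p = 0.168 for neurotrophic, 0.686 for morphogen and 0.561 for guidance ligands, and 0.561 for TGF-beta response genes). Each of the 3 lists lost its call without at least 1 library. Heart coculture 1 stood above every intestine coculture in 16 of 23 channels there and heart coculture 2 in 2, and without heart coculture 1 the camera adjusted p was 0.804 for the channels and 0.304 for cell cycle genes, while without heart coculture 2 it was 0.197 for the matrix genes. Without intestine coculture 4 it was 0.0609 for the channels and 0.0589 for cell cycle genes, and without intestine coculture 2 it was 0.0659 for cell cycle genes. With the date as a block the camera adjusted p of the cell cycle list there was 0.518, and axon guidance receptors (0.00491) and neurotrophic receptors (0.0268) also passed, Up.

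The count of 340 genes moved with the libraries and with the definition of neuron-like cells. It was 59, 81 and 70 without intestine coculture 2, 3 or 4, 143 and 142 without heart coculture 1 or 2, 8 with clusters named by their highest score alone, and 0 with only the 4 libraries whose dates were shared (edgeR, 735 at an unadjusted p under 0.05). With the date as a block 666 genes passed (657 higher, 9 lower), 313 of them among the 340. The fit of the 4 libraries had no block, while the blocked effect rests on the pairs that they form.

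Mesenchyme-like cells of the cocultures could be compared in 2 libraries of each kind. They were 47 of 8044 and 213 of 4866 cells in the heart cocultures. In intestine cocultures 1 and 3 they were 246 of 2274 and 38 of 2519 cells. They were a small part of the cells and do not stand for all organ cells. In camera 10 of 25 lists passed, and 0 passed with an estimated correlation (camera adjusted p of at least 0.533). Posterior Hox genes, which mark position along the body axis, were lower in the heart cocultures in 8 of 8 measured members, with a median log2 fold change of -7.17 (camera adjusted p = 1.08e-27). Hoxb6 stood at 55.3 and 37.0 CPM with intestinal cells and at 0 and 0.45 CPM with heart cells, and Hoxc6 at 50.6 and 39.5 against 0 and 0 CPM. The 4 measured hedgehog response genes were lower as a list (camera adjusted p = 0.00131), Foxf1, a transcription factor of gut mesenchyme, standing at 93.8 and 227 CPM against 10.5 and 6.11 CPM. BMP response genes were also down (camera adjusted p = 4.14e-05) and cardiac neuron subtype genes up (8.48e-06), and these 4 lists passed without each library in turn. The other 6 did not pass in at least 1 such fit. They were, down, dissociation stress (camera adjusted p = 0.00358, and 0.762 and 0.0579 without intestine coculture 3 or heart coculture 2) and anterior Hox genes (0.0151, and 0.944 and 0.375 without heart coculture 2 or intestine coculture 1), and, up, noradrenergic (0.0101, and 0.192 without intestine coculture 3), guidance ligand (0.0101, and 0.637 and 0.108 without intestine coculture 3 or heart coculture 1), voltage-gated channel (0.0134, and 0.762 and 0.697 without intestine coculture 3 or heart coculture 1) and extracellular matrix genes (0.0148, and 0.948 and 0.397 without intestine coculture 1 or heart coculture 2). Of the cardiac neuron subtype list only 3 of 8 members were measured, and these 3 were higher. Of 11 measured BMP response genes 10 were lower. Only 3 noradrenergic genes were measured, 2 higher and 1 lower. With the date as a block 12 lists passed, adding neurotrophic receptors (camera, Up, 0.00555) and morphogen ligands (camera, Down, 0.0139). The 8 posterior Hox genes passed adjusted over the list alone, but over all 11498 genes 0 passed (edgeR, 615 at an unadjusted p under 0.05), and DESeq2 called 195 and edgeR with the date block 71. With 38 to 246 cells per library, edgeR recovered 1% of simulated 4-fold changes, and the count was 537 and 403 without intestine coculture 1 or 3.

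Glia-or-progenitor-like cells of the cocultures could not be compared, since the cocultures held 19 of them, all with intestinal cells. The heart-minus-intestine difference of cocultured neurons was then set against that of E14.5 neurons taken from the heart and the intestine. Across 10532 genes, which are not independent replicates, Pearson's r was 0.0981, and 5 of the 15 ways to choose 2 of the 6 cocultures gave an r as large (exact permutation test, one-sided, p = 0.333, the smallest possible being 0.0667). Spearman's rho was -0.0018, r was -0.183 in cells with few organ markers, -0.061 with E14.5 heart library 1 alone and 0.272 with library 2 alone, where 1 of the 15 splits gave an r as large. It was 0.286 and -0.0742 without heart coculture 1 or 2 and -0.0025 without intestine coculture 1. Within the 2 shared dates r was 0.151 and 0.167. Neuron-like cells made up 17.1% ± 7.52 of cells with heart (n = 2) and 20.9% ± 8.76 with intestine (n = 4), a difference of -3.80 percentage points (exact permutation test, two-sided, p = 0.667, with no p under 0.05 possible), which became 1.52 without heart coculture 1.

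The second replicated comparison followed cardiac neurons from E12.5 to E14.5. As lists, synaptic vesicle, cholinergic and voltage-gated channel genes rose and Hox and Notch response genes fell. With camera's preset correlation 14 of 30 lists passed, and with an estimated one 0 passed (camera adjusted p of at least 0.374). Synaptic vesicle genes were higher at E14.5 in 19 of 19 members (median log2 0.72, camera adjusted p = 1.77e-11), as with Snap25, a vesicle fusion protein, at 316 ± 103 against 122 ± 8.10 CPM (n = 2 each). Voltage-gated channels were higher in 20 of 21 (median log2 1.11, camera adjusted p = 8.07e-12), with Scn9a, a sodium channel, at 58.4 ± 35.4 against 16.2 ± 6.71 CPM. E14.5 library 1 lay above both E12.5 libraries in 6 of these 21 channels and library 2 in 20, and without library 2 the median was 0.25 (camera adjusted p = 0.0146). Cholinergic genes were higher in 5 of 5 (camera adjusted p = 0.000679), with the choline transporter Slc5a7 at 63.3 ± 29.0 against 23.1 ± 3.04 CPM. Nitrergic and VIP genes were higher in 4 of 5 (camera adjusted p = 8.97e-05; 3 adjusted over the list alone). Anterior Hox genes were lower in 11 of 12 (median log2 -1.71, camera adjusted p = 4.4e-17; 10 adjusted over the list alone), with Hoxb2 at 17.3 ± 8.15 against 63.0 ± 14.4 CPM, and posterior Hox genes in 6 of 6 (median log2 -2.73, camera adjusted p = 6.19e-13; 5 adjusted over the list alone). Notch response genes were lower in 8 of 9 (camera adjusted p = 1.18e-08; 4 adjusted over the list alone), and so, by camera, were the lists of dissociation stress (adjusted p = 2.79e-05), retinoid response (0.000147) and autonomic transcription factors (0.00102). These 10 lists passed without each library in turn. The other 4 did not pass in 2 such fits each. Up were cytoskeleton and axon growth genes (camera adjusted p = 0.000606, and 0.0842 without E12.5 library 2 and 0.0596 without E14.5 library 1) and cardiac neuron subtype genes (0.0137, and 0.189 without E12.5 library 1 and 0.572 without E14.5 library 2). Down were FGF response (0.0016, and 0.113 without E12.5 library 2 and 0.266 without E14.5 library 1) and cell cycle genes (0.00503, and 0.219 without E12.5 library 2 and 0.0844, Up, without E14.5 library 2).

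Single genes were resolved in part. In all neuron-like cells 0 of 13835 genes passed (edgeR, 1023 at an unadjusted p under 0.05), while DESeq2 called 207. The genes nearest the threshold included Hes5, at 1.30 ± 0.87 CPM at E14.5 against 22.1 ± 7.16 CPM at E12.5 (edgeR adjusted p = 0.054). The share of neuron-like cells above 0.1% of organ marker UMIs was 6.71% and 8.68% at E12.5 but 1.90% and 45.3% in the E14.5 libraries. In cells below it, a restriction chosen after these shares had been seen, 50 of 13465 genes passed, 23 higher and 27 lower (edgeR, 1175 at an unadjusted p under 0.05). Hes5, a Notch target that keeps progenitors undifferentiated, fell from 21.5 ± 5.72 to 0.85 ± 0.22 CPM there (log2 -4.60 ± 0.42, edgeR adjusted p = 0.00405). Insm1, a transcription factor of newly born neurons, fell from 63.4 ± 16 to 9.52 ± 3.01 CPM (log2 -2.56 ± 0.37, edgeR adjusted p = 0.0242), as did Gfra1, a GDNF co-receptor (40.4 ± 17.4 to 6.58 ± 3.68 CPM, edgeR adjusted p = 0.0372), Sox2ot, St18, Sntb1, Igfbpl1, Dach2, Hoxb4 and Gpm6b. C1qtnf7, a secreted protein related to complement C1q, rose from 8.66 ± 2.78 to 67.2 ± 9.73 CPM (log2 3.13, edgeR adjusted p = 0.0132), Anxa2, a membrane-binding annexin, from 25.4 ± 7.26 to 193 ± 20.2 CPM, and Nrxn3, a synaptic adhesion protein, from 29.7 ± 2.30 to 237 ± 140 CPM, beside Dscaml1, Palmd, S100a6, Ptprt, Flrt1, Ano3 and Map7. Among list members Gucy1a1, a subunit of the nitric oxide receptor, and Rspo2 also rose, and Hoxb6 and Hoxb9 fell. Hes5 (ENSMUSG00000048001) lies on chromosome 4 at 154960923 to 154962371 and C1qtnf7 (ENSMUSG00000061535) on chromosome 5 at 43515538 to 43618803 of GRCm38. In all neuron-like cells the count was 47 and 37 without E12.5 library 1 or 2 and 2625 and 974 without E14.5 library 1 or 2, where the lone library was assumed to vary like the other group.

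**Figure D2:**
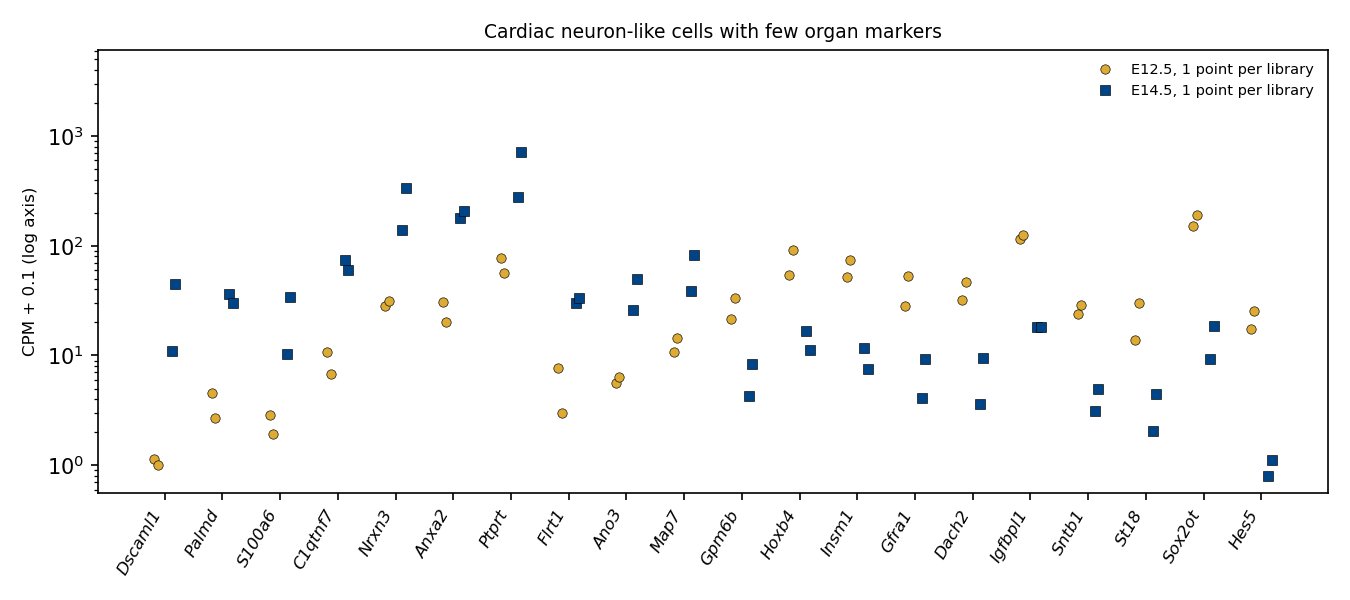
CPM on a log axis, with 0.1 CPM added, of the 20 named genes in cardiac neuron-like cells with few organ markers, 1 point per library, at E12.5 (n = 2) and E14.5 (n = 2). For each gene the libraries of the 2 ages did not overlap, as for Hes5, at 21.5 against 0.85 CPM on average.

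In glia-or-progenitor-like cells of the heart, Hox genes fell and matrix genes rose as lists between the same ages. List tests kept genes that failed the free-RNA test, and the restriction to few organ markers was run in neuron-like cells only. Among the neuron-like cells of the 2 E14.5 libraries, 1.90% and 45.3% held more than 0.1% organ marker UMIs. How far RNA of other cells adds to the lists of glia-or-progenitor-like cells was not tested. In camera 12 of 27 lists passed, and 0 passed with an estimated correlation (camera adjusted p of at least 0.577). Posterior Hox genes were lower in 6 of 6 members (median log2 -2.61, camera adjusted p = 2.16e-16; 5 adjusted over the list alone), with Hoxb8 at 2.47 ± 1.05 against 19.6 ± 0.64 CPM, and anterior Hox genes in 13 of 13 (median log2 -1.12, camera adjusted p = 9.13e-14; 3 adjusted over the list alone). Extracellular matrix genes were higher in 18 of 21 (median log2 1.03, camera adjusted p = 2.55e-14; 7 adjusted over the list alone), with Tnc, tenascin C, at 188 ± 167 against 14.7 ± 6.43 CPM. These 3 lists passed without each library in turn, with medians of 0.57 to 1.41 for extracellular matrix and -1.76 to -0.81 for anterior Hox genes. Further lists up in camera were voltage-gated channels (adjusted p = 0.00342), guidance ligands (0.0146), synaptic vesicle genes (0.0414) and neurotrophic ligands (0.0438), none of which passed without E14.5 library 2 (camera adjusted p of 0.187 to 0.795), nor synaptic vesicle genes without E12.5 library 1 (0.17). Those down were autonomic transcription factors (0.0261), retinoid response (0.0288), with Crabp2, a retinoic acid binding protein, at 31.1 ± 11 against 169 ± 5.90 CPM, FGF response (0.0288), noradrenergic (0.0475) and enteric sensory and interneuron genes (0.0475). None of these 5 passed without E14.5 library 1 (camera adjusted p of 0.0612 to 0.773), and 4 of them, all but the enteric list, did not without E12.5 library 2 (0.0858 to 0.964). The noradrenergic and enteric lists did not without E14.5 library 2 either (0.364 and 0.176). Of 13754 genes 0 passed (edgeR, 790 at an unadjusted p under 0.05), and DESeq2 called 198. The count was 86 and 23 without E12.5 library 1 or 2 and 3354 and 358 without E14.5 library 1 or 2.

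Neurons of 4 organs were set side by side at E14.5. Only the heart had 2 libraries, so no test was made, and intervals in parentheses are exact 95% Poisson intervals that cover counting error only. The heart libraries came from a Wnt1-Cre line and the others from a Phox2b-Flpo line, so that driver and organ cannot be told apart. In the heart, Igfbp7, an insulin-like growth factor binding protein, stood at 140 (137 to 144) and 82.2 (77.2 to 87.3) CPM, and at 1.58 (1.23 to 2.01) in the intestine, 4.83 (3.97 to 5.82) in the lung and 4.31 (3.60 to 5.12) in the pancreas. Npas2, a clock transcription factor, stood at 8.93 (8.13 to 9.79) and 11.8 (9.99 to 13.9) CPM in the heart and at 0.28 (0.15 to 0.50) or less elsewhere, and the orexin receptor Hcrtr2 at 8.09 and 9.66 CPM against 0.94 or less. Vip, the vasoactive intestinal peptide, stood at 13.47 (12.48 to 14.51) and 23.9 (21.2 to 26.7) CPM in the heart against 348, 174 and 232 CPM in intestine, lung and pancreas, and Nos1, the neuronal nitric oxide synthase, at 1.06 (0.80 to 1.38) and 1.12 (0.61 to 1.88) against 26.5, 7.29 and 30.6 CPM. Cxcr4, a chemokine receptor of migrating cells, stood at 0.10 and 0.56 CPM against 12.51 CPM or more. Of the 5 measured nitrergic and VIP genes, 2 were lower in the heart by the rule of size, and the list's median log2 difference of -1.66 was at percentile 0 of 10000 random lists matched on expression. Of 26 cell cycle genes 5 were higher (median 1.25, percentile 100). The random lists drew each gene on its own, while genes of a list can vary together and are not replicates. These percentiles, here and below, are therefore not p-values. By the same rule 33 genes were higher and 11 lower in the heart. Among the heart's neuron-like cells, 1.90% and 45.3% held more than 0.1% organ marker UMIs.

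Intestinal neurons met this rule for the most genes, with 158 higher and 63 lower. The counts per organ are not on equal terms. A heart gene had to differ in 2 libraries, and the lung and pancreas libraries shared a title date. The intestinal library also had a median of 3282 UMIs per barcode, against 8065 to 17687 in the other libraries. These points were not tested as sources of the counts. Klhl1, a neuronal kelch protein, stood at 174 (170 to 178) CPM against 1.36 (0.79 to 2.17) or less in each other library. Hoxb5 stood at 557 (550 to 564) against 13.3 (11.8 to 14.8) CPM or less, Hoxa5 at 394 (388 to 400) against 5.12 (4.52 to 5.78) CPM or less and Hoxb6 at 84.5 (81.8 to 87.4) against 1.20 (0.67 to 1.98) CPM or less. Hoxa3 was also higher, but its annotated span covers Hoxa5 on the same strand, so its counts are uncertain. Of 14 anterior Hox genes 10 were higher in the intestine (median log2 difference 2.10, percentile 100 of the matched random lists). Isl1, a transcription factor of sympathetic and sensory neurons, stood at 2.48 (2.03 to 3.00) CPM in the intestine against 949, 616, 527 and 139 CPM in heart 1, heart 2, lung and pancreas. Gata3, another factor of the sympathetic lineage, stood at 0.69 (0.46 to 0.98) against 174, 147, 49.1 and 44.5 CPM, and Sytl4, which acts in granule exocytosis, at 0.54 (0.34 to 0.82) against 182, 160, 49.3 and 78.7 CPM. Of 26 cell cycle genes 11 were lower (median -1.46), and noradrenergic genes had a median of -1.26.

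Lung and pancreatic neuron-like cells had 7 and 6 genes higher and 2 and 15 lower. With neurons defined cell by cell from markers, the ratios of Aplnr, Sox18 and Cdh5 in the lung turned. So did those of Cpa1, Ctrb1, Clps, Pnliprp1, Spp1 and Kdr in the pancreas. Cdh5 is among the fixed markers of endothelium, and Cpa1 and Ctrb1 are among those of pancreatic cells. The counts can thus not be taken as traits of the neurons alone. Socs3, a feedback inhibitor of cytokine signalling, stood at 101 (97.1 to 105) CPM in the lung against 15.4 (13.3 to 17.7) or less, with 179 CPM in the other cells of the lung library. Cartpt, a neuropeptide precursor, stood at 42.2 (39.6 to 44.9) CPM in the lung against 178 CPM or more. In the pancreas the digestive enzyme genes Cpa1, at 16.2 (14.8 to 17.7), and Ctrb1, at 8.32 (7.31 to 9.42) CPM, led the list, and both were at 0 in neurons defined cell by cell from markers. Lower in the pancreas were Ngfr, a neurotrophin receptor, at 5.22 (4.43 to 6.11) against 29.4 CPM or more, and Hoxc4, at 3.84 (3.17 to 4.61) against 22.5 CPM or more.

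**Figure D3:**
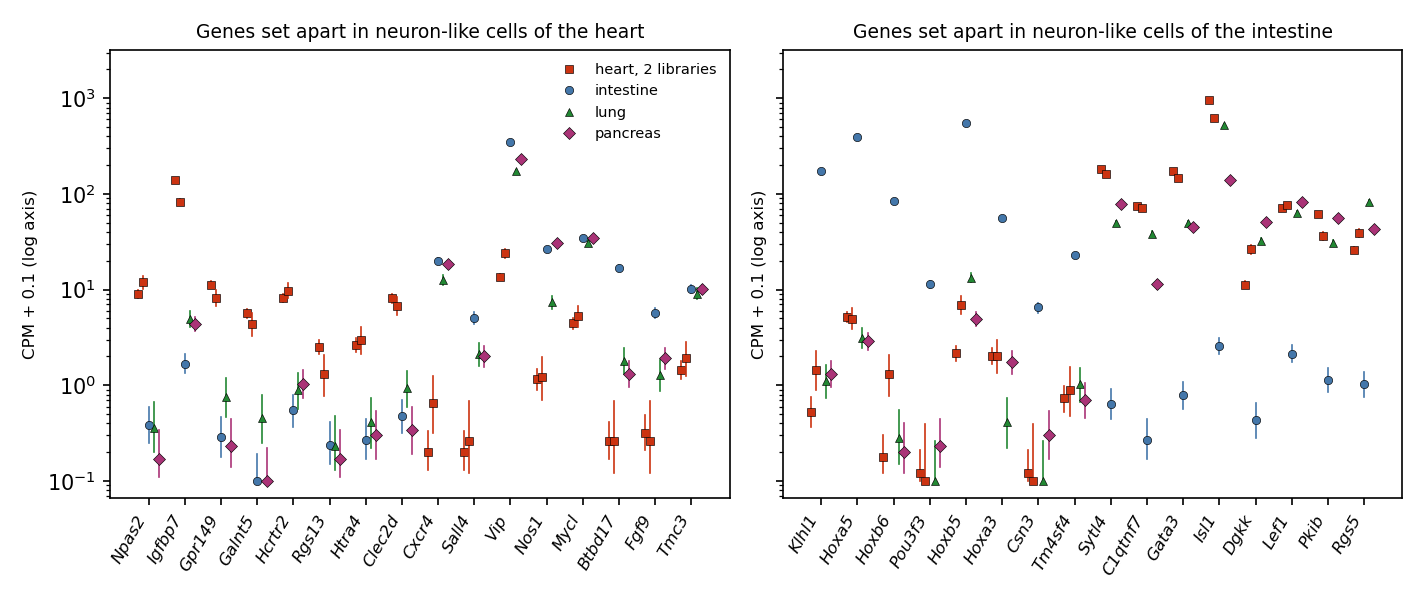
CPM on a log axis, with 0.1 CPM added, of genes named for the heart and for the intestine in neuron-like cells of E14.5 libraries, 1 point per library, with exact 95% Poisson intervals as lines. Klhl1 stood at 174 CPM in the intestine and at 1.36 CPM or less in each of the other 4 libraries.

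Cardiac neurons were then followed to later ages, with 1 library per age and no test. The E18.5 and P56 libraries came from a Baf53b-Cre line and a density gradient, unlike those of E16.5 and earlier. From E14.5 to E16.5 few genes met the rule of size, 16 higher and 35 lower. Cidea, a lipid droplet protein, stood at 74.6 (72.1 to 77.1) CPM at E16.5 against 4.44 and 5.67 CPM at E14.5, and Lox, the collagen crosslinking enzyme, at 54.9 (52.8 to 57.0) against 2.69 and 9.66 CPM. The histone gene Hist1h2ap stood at 19.7 against 139 and 215 CPM, and 7 of 26 cell cycle genes were lower. From E16.5 to E18.5, 421 genes were higher and 322 lower. Calca, the precursor of calcitonin gene-related peptide, stood at 105 (103 to 108) against 0.47 (0.30 to 0.71) CPM, Ntrk1, the nerve growth factor receptor, at 45.1 (43.4 to 46.8) against 0.19 (0.09 to 0.37) CPM, and Slc17a6, a vesicular glutamate transporter, at 9.61 (8.86 to 10.4) CPM against 0, at least 150-fold higher by the floor of 3 counts. At E18.5, 98.5% of Calca and 98.7% of Slc17a6 UMIs lay in a cluster of 31 of the 1193 neuron-like cells. Cck, the cholecystokinin precursor, stood at 0.13 against 28.3 CPM. Of 26 cell cycle genes 24 were lower at E18.5, and higher were 12 of 19 neuropeptides and 7 of 8 cardiac neuron subtype genes.

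At P56 against E18.5, 246 genes were higher and 1128 lower. The noradrenaline transporter Slc6a2 stood at 0.02 (0 to 0.06) CPM at P56 against 26.2 (25.0 to 27.5), Igf2bp1, an RNA-binding protein of fetal tissue, at 0.04 against 12.9 CPM, and Shox2, a transcription factor of the sinoatrial region, at 0 against 12.8 CPM, at least 536-fold lower by the floor of 3 counts. At E18.5, 97.6% of Slc6a2 UMIs lay in 1 cluster. Psmb8, an immunoproteasome subunit, stood at 40.2 (39.1 to 41.4) against 0.32 CPM. The lung secretory genes Scgb1a1 and Sftpc stood at 89.4 and 18 CPM at P56 and at 0 at E18.5. Lower by the rule for lists were 16 of 28 autonomic transcription factors (median log2 difference -0.97), 12 of 21 axon guidance receptors (median -0.94) and 12 of 19 neuropeptides.

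Atrial tissue near the intracardiac neurons was compared with atrial tissue far from them, with 1 library each. Neuron-like cells made up 5.09% (exact binomial interval 4.63 to 5.58) of cells near and 0.147% (0.07 to 0.27) far, and mesenchyme-like cells 47.6% (46.5 to 48.7) and 21% (20.04 to 22). The dissection had set these areas apart by labelled cells of the nervous system, which can set the neuron-like share. Endothelium-like cells made up 9.77% near and 21.02% far. The far library also held 2.29% erythroid-like cells, a class not found near, and 6.41% unnamed cells against 0.737% near. Whether tissue other than atrium had been taken along was not tested for the differences below. Cardiomyocyte-like cells differed in 267 genes higher and 275 lower near. Nppa, the atrial natriuretic peptide, stood at 9.0 (8.27 to 9.77) CPM near against 961 (953 to 969) far, Bmp10, a ligand of trabecular myocardium, at 0.02 against 4.71 CPM, and Ntn1, the guidance cue netrin 1, at 0.62 (0.44 to 0.85) against 43.3 (41.6 to 45.0) CPM. Ntsr1, the neurotensin receptor, stood at 49.8 (48.0 to 51.6) against 0.84 (0.62 to 1.11) CPM and Fabp4, a fatty acid binding protein, at 243 (239 to 246) against 4.62 CPM. Among endothelium-like cells, with 93 genes higher and 42 lower near, Foxf1 stood at 30.5 (27.7 to 33.5) against 0.80 (0.52 to 1.19) CPM and 8 of 10 anterior Hox genes were higher near. Among mesenchyme-like cells, with 76 higher and 65 lower, Lsamp, a neuronal adhesion protein, stood at 1545 (1535 to 1556) against 132 (127 to 136) CPM, and Wif1, a secreted Wnt inhibitor, at 1.64 against 15.5 CPM.

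Ligands of organ cells at E14.5 were compared between the atrium, near and far, and the intestine. Gdnf, the glial cell line-derived neurotrophic factor, stood at 0.06 (0.03 to 0.12) and 0.07 (0.03 to 0.12) CPM in all non-neuronal atrial cells, near and far, against 18.3 (17.5 to 19.2) CPM in those of the intestine. These sums pool unlike cells. The intestine library held 38.9% smooth-muscle-like and 34.4% epithelium-like cells, and the atrial libraries 30.4% and 37.2% cardiomyocyte-like cells. A different mix of cells can therefore not be told apart from a difference within a cell type. In mesenchyme-like cells, Ptn, the growth factor pleiotrophin, stood at 7768 and 6280 CPM against 219 (210 to 228), Tgfb2 at 156 and 274 against 6.25 (4.79 to 8.01), Slit2, a repellent guidance cue, at 379 and 1147 against 57.1, and Ngf at 48.7 (46.9 to 50.6) and 36.0 (33.8 to 38.3) against 7.96 (6.30 to 9.92) CPM. Higher in the intestinal mesenchyme-like cells were Bmp4, at 407 against 27.4 and 49.1 CPM, Bmp5, at 183 against 2.94 and 5.47 CPM, and Nrg1, a ligand of ERBB receptors, at 328 against 37.1 and 41.7 CPM. Among the mesenchyme-like cells 5 of 18 neurotrophic ligands were higher and 6 lower in the atrium, as were 7 and 4 of 19 guidance ligands and 10 and 11 of 35 morphogen ligands. The comparison had no replicates, and the atrial and intestinal libraries came from different driver lines. Its ligands were taken without the test for free RNA of other cells.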

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

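Of the tests below, those of the title date and of a response of the neurons, and both tests of the E18.5 genes, were chosen only after the result was seen. The tests with few organ markers and with random removals had their bounds written before their values, but after the 340 genes and the marker shares had been seen.

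Ptgis, a prostacyclin synthase, and Spon2, a secreted matrix protein, each had 1 intestine coculture far from the other 3 in neuron-like CPM, with gaps of 0.863 and 0.894 of the range, beyond Dixon's 95% critical value for 4 samples. Of 12 genes and shares tested 2 stood out, and chance alone marks about 1 in 20. Epithelium-like cells made up 58.7% of the cells of E12.5 library 1, where labelled cardiac cells had been sorted, and 4.19% of E12.5 library 2. They enter no comparison as a class. Their RNA in neuron-like droplets is not covered by the restriction to few organ markers, which counts no epithelium markers.

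The 340 genes of cocultured neurons were all higher with heart cells. Random removal of as many cells left their median log2 fold change at 3.46, which argues against the smaller number of cells. With the date as a block 657 genes were higher and 9 lower. This argues against the date as the whole cause, but rests on the pairs of shared dates alone. In the 4 libraries of shared dates, fitted without a block, 0 passed (edgeR, 735 at an unadjusted p under 0.05). RNA of organ cells in neuron-like droplets may account for much of the pattern, since in cells with few organ markers the median of the 252 genes tested was 0.81 (quartiles 0.41 and 1.51) in place of 3.08, and 0.79 in place of 2.99 without the markers themselves, although the restriction also removes any neuron that expresses such genes. A response of the neurons to cardiac cells stays open, since 0 of the 340 genes passed both the threshold and the free-RNA test there (1 with the date as a block), where edgeR called 0 genes, 193 had an unadjusted p under 0.05 and DESeq2 called 32. The clusters that the naming rule kept out in the intestine cocultures alone are a further open point, since only 8 genes passed with clusters named by their highest score.

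Between E12.5 and E14.5 cardiac neuron-like cells, 0 genes passed in all cells (edgeR, 1023 at an unadjusted p under 0.05; DESeq2 called 207) and 50 in cells with few organ markers. Random removals of as many cells gave a median count of 5.5 (0 to 15). This is consistent with RNA of organ cells, at 45.3% of neuron-like cells in E14.5 library 2 against 1.90% in library 1, adding spread between the libraries of that age. The other year in the title of E14.5 library 1 was not tested as a source of that spread.

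Calca, Slc17a6, Calcb, Ntrk1 and 4 other genes stood far higher in cardiac neurons at E18.5 than at E16.5. The cluster with most of a gene's UMIs held a median of 89.3% of them over these genes, with the lowest share for Irs3 at 33.9%, and no such cluster held over 20.5% of the neuron-like cells. The pattern may thus come from a few groups of cells, such as the 31 cells that held 98.5% of Calca UMIs, which could be another neuron type or another ganglion taken along. The other driver line and the density gradient cannot be told apart from the age, since 0 libraries of E18.5 were made with the earlier line.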

How the results depend on the processing

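Alternatives with cells of few organ markers, clusters named by their highest score alone, the 4 libraries with shared dates, 1 class for all stromal cells, correlations within dates and gene lists with each library left out were chosen after seeing the data; the others were planned. The 340 genes of cocultured neurons became 714 with DESeq2, 588 with a replicate block by number, 666 by date, 117 with doublets kept, 220 at Leiden resolution 2, 37 with classes by markers and 8 by highest score alone. They became 0 with the 4 libraries of shared dates (edgeR, 735 at an unadjusted p under 0.05). Without 1 library each they ranged from 59 (intestine coculture 2) to 480. In cells with few organ markers 0 genes passed (edgeR, 193 at an unadjusted p under 0.05), 146 with the date as a replicate block, 32 with DESeq2, and 0 to 1 without 1 library each. DESeq2 size factors (332), no filter (410), the free-RNA test first (287) and the stricter cell filter (404) stayed within 1.5 times. The 10 named genes stayed higher under each. Past the threshold were 7, 8 and 8 without intestine coculture 2, 3 or 4, 9 without heart coculture 2, 10 without either other library, 9 with no filter, 8 with the date block, 4 with doublets kept, 5 with classes by markers, 2 by highest score and 0 with the 4 libraries of shared dates. Of the 9 tested with few organ markers 0 passed in edgeR, 8 with the date block and 7 with DESeq2.

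The count of 0 in coculture mesenchyme-like cells (615 at an unadjusted p under 0.05 in edgeR) became 195 with DESeq2, 420 with no filter, 71 with the date as a replicate block, 20 with the stricter cell filter, 761 with classes by markers, 924 with all stromal cells as 1 class, and 0 to 537 without 1 library each. The count of 0 in cardiac neuron-like cells (1023) became 207 with DESeq2, 354 with no filter, 6 with the free-RNA test first, 1 with classes by markers and 50 in cells with few organ markers, and that of glia-or-progenitor-like cells (790) 198 with DESeq2 and 374 with no filter. Without 1 library each these ranged from 37 to 2625 and from 23 to 3354. With the number as a replicate block the counts were 579 and 275. The 2 pairs of cardiac libraries share only a number, and same-numbered libraries correlated at 0.42 in neuron-like and 0.044 in glia-or-progenitor-like cells. Both pairs give the same value by construction, since the deviations of 2 libraries from their mean mirror each other. The coculture mesenchyme-like libraries shared only 1 number, so that their block was the date alone. The comparisons of the later ages, regions and organs came from no test, so they had no block. The comparison of coculture glia-or-progenitor-like cells was not run, for want of cells. Of the 41 lists that passed camera's test 0 passed with an estimated correlation, and 50 passed with the blocks. The date block changed no call other than those given beside the results, 27 of 27 list members past the threshold in cocultured neurons passing with it, and with the number as a block 17 lists passed in cardiac neuron-like and 13 in glia-or-progenitor-like cells. Without 1 library each, 5 to 9 lists passed in cocultured neurons (5 with all), 8 to 12 in coculture mesenchyme-like cells (10), 12 to 20 in cardiac neuron-like cells (14) and 9 to 16 in glia-or-progenitor-like cells (12), and 5, 4, 10 and 3 of those with all libraries passed every time. In cocultured neurons with few organ markers 1 to 6 passed (3 with all), and 0 of the 3 every time.

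The correlation of 0.0981 became -0.0018 as Spearman's rho, -0.061 with E14.5 library 1 alone, 0.272 with library 2 alone (1 of 15 splits as large, exact permutation p = 0.0667, the smallest possible), 0.217 with doublets kept, -0.1833 with few organ markers, -0.1919 with the free-RNA test added, and -0.0756 and -0.0306 there within the shared dates. Without 1 library each it ranged from -0.0742 (heart coculture 2) to 0.286, with -0.0025 without intestine coculture 1. The difference in neuron-like share of -3.80 points ranged from -9.12 (without heart coculture 2) to 1.52 (without heart coculture 1) without 1 library each, and from -9.18 (clusters by highest score alone) to -1.79 (doublets kept) under the other alternatives. Counts of genes by the rule of size (295, 2168, 1101 and 79) stayed within 1.5 times in each alternative run. The last of these counted ligands, at a ratio of at least 2 and without the free-RNA test. Of 291 genes named without replicates, ratios turned with classes by markers for Aplnr (0), Sox18 (0.171) and Cdh5 (0) in the lung, Cpa1 (0), Ctrb1 (0), Clps (0), Pnliprp1 (0), Spp1 (0.612) and Kdr (0.959) in the pancreas, Reg3g (0.331) at P56, Pgam2 (0.466), Vsnl1 (0.582) and Wfdc18 (0.528) near against far, and Fgf18 (0.641) and Rspo1 (0.887) in atrial mesenchyme. The ratio moved beyond its counting interval without turning for 145 genes with doublets kept (129 stayed within), 131 with classes by markers (144 within) and 122 with the stricter filter (168 within). With doublets kept some of the 291 genes had no value, since their class was missing from a library. Mpo turned in 3 settings (0.27 with doublets kept, 0.272 with the stricter filter, 0.277 with classes by markers). The cause was not tested for any of these. With 38 to 246 mesenchyme-like cells per coculture, 1% of simulated 4-fold changes were recovered there.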

Other observations

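The cluster shares of this part were computed only after the data were seen. Cardiac neuron-like cells of E18.5 fell into groups with different transmitter genes. Of the UMIs of Slc6a2, the noradrenaline transporter, 97.6% lay in a cluster of 130 of the 1193 cells, which also held 62.3% of the UMIs of Dbh, the enzyme that makes noradrenaline, and 40.8% of those of Th, the first enzyme of that pathway. Cma1, a mast cell protease gene, had 98.9% of its UMIs in a cluster of 244 neuron-like cells that also held 41.3% of the UMIs of the neuropeptide gene Npy. Chat, the acetylcholine-making enzyme, was spread more widely, with 23.9% of its UMIs in the cluster that held most of them. Genes here other than Cma1 were chosen after their values were seen.

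Melanocyte-like cells made up 9.99% and 20.9% of the E12.5 cardiac libraries, 10.5% and 5.74% of those of E14.5 and 6.32% of that of E16.5, which were all made with the Wnt1-Cre line. In immune-like cells of the atrium, Clec4f, a gene of liver macrophages, stood at 0.39 (exact 95% Poisson interval 0.01 to 2.16) CPM near the intracardiac neurons against 105 (94.5 to 117) CPM far from them, and Marco, a scavenger receptor, at 0 against 74.7 CPM, at least 64.2-fold lower by the floor of 3 counts. In endothelium-like cells Pcdh15, a cadherin of hair cells, stood at 181 (174 to 188) against 2.19 (1.70 to 2.77) CPM. The far library also held 2.29% erythroid-like cells, a class not found near, and 6.41% unnamed cells against 0.737% near. Whether liver cells had entered the far library was not tested. The Clec4f and Marco values can thus not be taken as a trait of atrial immune cells. In non-neuronal cells, whose sums pool unlike cell types, Wnt2 stood at 10.6 and 31.8 CPM in the atrium near and far against 0.14 (0.08 to 0.23) CPM in the intestine.

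Of the 30 lists in cocultured neurons 25 did not pass in camera. Among them enteric excitatory genes had a median log2 fold change of -0.84 (6 of 6 lower with heart cells, camera adjusted p = 0.225), cholinergic genes one of 0.08 (camera adjusted p = 0.979) and noradrenergic genes one of 0.08 (camera adjusted p = 0.764). Of the noradrenergic, cholinergic, and nitrergic and VIP lists 0 genes passed over all genes tested (edgeR), and Gucy1a1 alone passed adjusted over its list (edgeR adjusted p = 0.0146).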
